A study of Homo sapiens with 9 samples.

How the data were processed

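RNA abundance was measured by sequencing in 9 libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, cells were transfected for 36 h with 10 nM of a negative control siRNA, of an siRNA against PHF12 or of an siRNA against SUDS3, with 3 libraries per siRNA. The labels name 1 siRNA per target, whose sequences are not given in the sources used here. RNA was extracted with TRIzol, treated with DNase and made into stranded poly-A libraries with an Illumina TruSeq kit. The tools named by the authors are Trimmomatic 0.36, HISAT2 2.1.0 and HTSeq, with genome build GRCh38, and the strand setting used in counting is not given in the sources used here.

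The authors deposited a table of counts, whole numbers for 58735 genes, and a table of TPM, a measure scaled for transcript length in which each library sums to 1000000. All 58735 gene identifiers are in GENCODE 29, which gave symbols, gene types and GRCh38 coordinates. The TPM table lacks 1 gene, which has a total count of 8. Of the counts above 0, 96.1% are multiples of 4, against 25.0% by chance, and so are 99.7% of the counts from 1 to 50, so 1 sequenced fragment appears to be worth 4 counts. At that ratio, library totals of 37962926 to 50946148 counts would come from 4 times fewer fragments. The dispersion estimated between libraries can take up part of this inflation in the tests, but none in the low-count filter. Its minimum count of 10 would stand for 4 times fewer fragments, so genes with few fragments were tested. A repeat with counts divided by 4 is among the alternatives. It changed the tests as well: the edgeR adjusted p of SUDS3 in the SUDS3 knockdown was 5.57e-47 there, against 1.82e-28 with counts as deposited.

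Groups were taken from the labels. The labels do not say whether replicates were separate cultures, so each p measures the spread between these libraries. No pair of libraries within a group was identical, and their differences exceeded counting error, with a chi-square per degree of freedom of 1.38 to 2.21. Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10, TMM scaling, a quasi-likelihood model with robust shrinkage and a mean for each of the 3 groups, and F-tests of 3 contrasts (each knockdown against control, and SUDS3 knockdown against PHF12 knockdown). In total 18088 genes were tested. The Benjamini-Hochberg method adjusted p within each contrast, and genes with an adjusted p under 0.05 passed. Fold changes are on the log2 scale with standard errors (SE) from the F-statistic. Levels are counts scaled by TMM to 1000000 per library (CPM), given as mean ± SD of 3 libraries. Tested on simulated counts for 17719 genes, with 50 genes changed at each size, the fit recovered 34 and 36 of the genes changed 2-fold with the PHF12 and the SUDS3 arm, 40 and 43 of those changed 3-fold and 26 and 24 of those changed 1.25-fold. False calls numbered 4 of 127 and 8 of 139.

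The contrasts, the gene lists, the rule for named genes and the alternatives not marked as added were chosen before the data were examined. The 32 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast. Camera asks whether a list's genes moved more than other genes. It was repeated with an estimated correlation, and fry tested whether a list's genes moved one way on balance. Named genes are PHF12 and SUDS3, and the 10 largest rises and falls in each knockdown among protein-coding genes that passed, had an average log2 CPM of at least 1 and had all 3 knockdown libraries on 1 side of all 3 controls. They also include the 5 largest each way between the knockdowns, the 3 members with the smallest p of each list that passed, every SIN3 complex subunit that passed, and the 5 with the largest combined change among genes that rose in both, fell in both or moved in opposite directions. This rule gives 114 genes, some of which are not reported here. REST and RCOR1 were chosen after their values were seen. Of these genes and REST, 41 overlap a tested gene on the opposite strand, 13 overlap one on the same strand and 25 have pseudogenes named after them, so their counts can include reads of other genes.

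Both knockdowns share the same 3 control libraries, which adds similarity between their fold changes. The overlap was therefore set beside 20 simulations of unchanged groups against the same controls.

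Chosen after the data were examined, a scan looked for siRNA seed matches, the short sites through which an siRNA can act on transcripts other than its target. It scored 16222 heptamers in the longest annotated 3' UTR of 11625 protein-coding genes against the fold changes, with 3' UTR length, base composition and expression level regressed out. A score z is the mean residual of the genes with the heptamer in units of its standard error. Permuted fold changes gave an absolute z of at most 3.85, and the scan found the moved heptamer in 5 of 5 tests on simulated shifts. Intervals of 95% for differences in medians come from 1000 bootstrap draws over genes, which are not independent replicates.

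Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, no robust shrinkage, replicate number as a block, fits of 2 groups only, DESeq2 1.42.0, limma 3.58.1 on log2 TPM with pseudocounts of 1 and 0.1 or without the filter of 1 TPM in 3 libraries, and leaving out each library. Counts divided by 4, genes whose 3' UTR holds none of the 3 leading hexamers, and for the covariance a minimum average log2 CPM of 1 were added after the data were examined. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.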

Results

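The series gives gene expression in HEK293T cells after transfection with siRNA, to study what PHF12 and SUDS3 do in these cells. Both proteins are subunits of SIN3 histone deacetylase complexes, which repress transcription. The 3 control libraries held 44192754, 46604093 and 37962926 counts in total, the 3 PHF12 knockdown libraries 48283643, 50946148 and 43334054, and the 3 SUDS3 knockdown libraries 43203503, 47332744 and 40489654. The mitochondrial share of counts lay between 4.98% and 5.67% in all 9 libraries. In a principal component analysis, PC1 held 58.7% of the variance and set PHF12 knockdown libraries at one end and SUDS3 knockdown libraries at the other. PC2 held 26.0% and set the controls apart from both knockdowns.

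Each siRNA lowered the transcript of its target. PHF12 (ENSG00000109118, GRCh38 chromosome 17, 28905250 to 28951771) fell from 49.9 ± 0.938 CPM in controls to 26.9 ± 2.09 CPM in the PHF12 knockdown, which left 53.9% (SD, n = 3; log2 fold change -0.89, SE 0.06, edgeR adjusted p = 1.88e-14). SUDS3 (ENSG00000111707, chromosome 12, 118376380 to 118418031) fell from 111.1 ± 3.31 to 22.1 ± 0.937 CPM in the SUDS3 knockdown, which left 19.9% (log2 fold change -2.33, SE 0.05, adjusted p = 1.82e-28). The targets also changed in the other knockdown. PHF12 rose to 61.5 ± 1.73 CPM with the SUDS3 siRNA (log2 fold change 0.30, adjusted p = 7.19e-05). SUDS3 fell to 81.0 ± 0.784 CPM with the PHF12 siRNA (log2 fold change -0.46, adjusted p = 6.83e-10), and its 3' UTR holds the hexamer AATCAC that led the heptamer scan of falls in that knockdown.

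**Figure D1:**
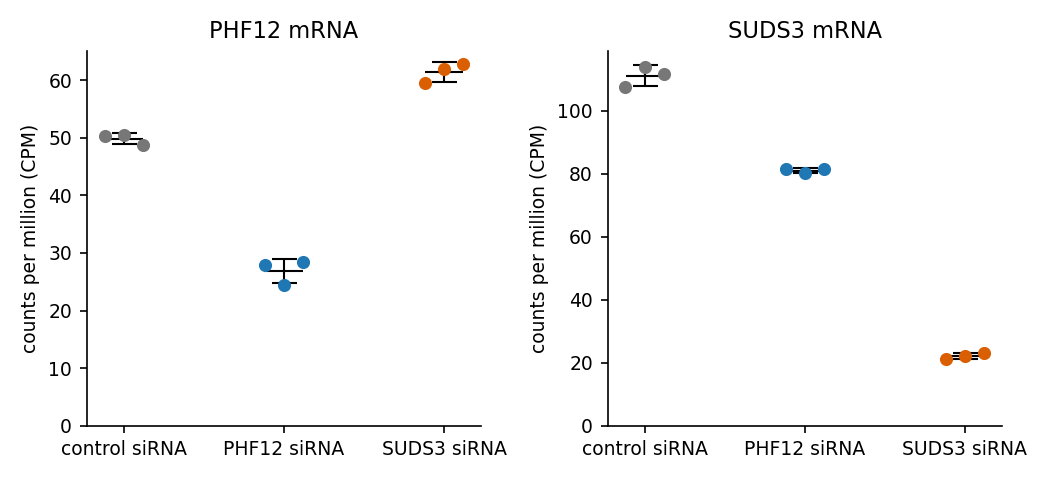
TMM-scaled CPM of PHF12 and SUDS3 in each of the 9 libraries (points), with the mean (line) and SD (bar) of 3 libraries per siRNA. The 3 PHF12 knockdown libraries lay between 24.5 and 28.3 CPM for PHF12, and the 3 SUDS3 knockdown libraries between 21.1 and 23.0 CPM for SUDS3.

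The comparison of PHF12 knockdown with control asks which transcripts depend on the PHF12 siRNA. In camera at the preset correlation, HOX genes, which encode transcription factors of body patterning, and ribosomal protein genes rose as groups, and genes of the unfolded protein response and amino acid stress response, of cholesterol synthesis and of the NRF2 oxidative stress response fell. With an estimated correlation these calls were lost, with an adjusted p of 0.0641 for HOX, 0.4 for ribosomal protein and 0.264 for stress response genes, and of 0.0937 for cholesterol and for NRF2 genes. The largest fall was that of HMGA2 (ENSG00000149948, chromosome 12, 65824131 to 65966295), a chromatin architectural protein, from 91.4 ± 1.48 to 11.7 ± 0.586 CPM (log2 fold change -2.97, SE 0.06, adjusted p = 1.02e-29). The largest rise was that of SLC4A8 (ENSG00000050438, chromosome 12, 51391317 to 51515763), a sodium-driven bicarbonate transporter, from 2.63 ± 0.405 to 12.96 ± 1.39 CPM (log2 fold change 2.29, SE 0.16, adjusted p = 2.25e-14). Of 18088 genes, 2680 rose, 3096 fell and 12312 did not pass, and at least 2-fold changes numbered 121 rises and 240 falls. Rises made up 46.4% of the calls with TMM scaling and 56.9% with upper-quartile scaling.

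Behind SLC4A8, the largest rises with the PHF12 siRNA were in SYT11 (log2 fold change 1.91), a synaptotagmin of vesicle traffic, C16orf45 (1.74), the sodium channel subunit SCN4B (1.62), the microtubule-binding MAP6 (1.59), the actin-binding CORO1A (1.51), LMLN (1.42), TMEM59L (1.37), the melanosome protein PMEL (1.33) and HOXC12 (1.32). Their adjusted p ran up to 0.000174, that of PMEL. Behind HMGA2, large falls were in the ubiquitin-conjugating enzyme UBE2E2 (-2.30), the death-domain adaptor CRADD (-2.11), DDAH1 (-2.05), which degrades methylated arginine, the zinc transporter SLC39A6 (-1.84), the complexin CPLX1 (-1.81), the kinase PRKX (-1.81), TPD52 (-1.78) and glutathione reductase, GSR (-1.72). The PHF12 scan's hexamer AATCAC was in the 3' UTR of 9 of the 10 largest falls, all except CRADD, and of 2 of the 10 largest rises. That hexamer was picked from the same fold changes.

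Of 38 HOX genes tested, 24 rose with the PHF12 siRNA, 2 fell and 12 did not pass, the same as adjusted over the list alone. Their median log2 fold change was 0.38 (camera adjusted p = 1.45e-07, and adjusted p = 0.0641 with an estimated correlation). HOXA9 rose from 112.0 to 178.1 CPM (log2 fold change 0.67), HOXA5 by 0.53 and HOXA10 by 0.47, each in a cluster where neighbouring transcripts overlap. Among 78 ribosomal protein genes, 53 rose, 4 fell and 21 did not pass (56 rose and 5 fell adjusted over the list alone), with a median of 0.12 (adjusted p = 3.53e-06, and adjusted p = 0.4 with an estimated correlation). RPLP0 rose by 0.49, RPS25 by 0.23 and RPL13A by 0.20, and all 3 have pseudogenes that can share reads. The stress response list, 33 genes of the integrated stress response and the unfolded protein response, had 23 falls, 2 rises and 8 genes that did not pass (24 fell and 2 rose adjusted over the list alone), with a median of -0.23 (adjusted p = 3.29e-07, and adjusted p = 0.264 with an estimated correlation). The endoplasmic reticulum chaperones HYOU1 (-0.43) and DNAJC3 (-0.62) and the serine synthesis enzyme PSAT1 (-0.45) fell.

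Of 17 NRF2 targets, 8 fell, 0 rose in edgeR and 9 did not pass (9 fell and 1 rose adjusted over the list alone, 1 rose at an unadjusted p under 0.05 and 1 rose in DESeq2), with a median of -0.13 (camera adjusted p = 2.86e-05, and adjusted p = 0.0937 with an estimated correlation). They included GSR and the cystine transporter SLC7A11 (-0.80). Of 25 genes of cholesterol synthesis and LDL uptake, 13 fell, 1 rose and 11 did not pass (14 fell and 1 rose adjusted over the list alone), with a median of -0.20 (adjusted p = 0.00389, and adjusted p = 0.0937 with an estimated correlation). DHCR7 fell by 0.52 on the log2 scale, LSS by 0.48 and SREBF2, the transcription factor of the pathway, by 0.43. In fatty acid synthesis 5 of 14 genes fell, 2 rose and 7 did not pass (6 fell and 3 rose adjusted over the list alone), with a median of -0.09 (adjusted p = 0.00409, and adjusted p = 0.223 with an estimated correlation). ELOVL5 fell by 0.90, SCD from 833.7 to 537.4 CPM (-0.63) and ACLY by 0.16. Among 29 neuronal genes repressed by the silencing factor REST, 11 fell, 4 rose and 14 did not pass, the same as adjusted over the list alone, with a median of -0.41 (adjusted p = 0.0129, and adjusted p = 0.119 with an estimated correlation). NPTX1 fell by 1.41, the stathmin STMN3 by 0.99 and synaptophysin, SYP, by 0.82.

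With the PHF12 siRNA, camera called 7 of 32 lists, and 0 of 32 with an estimated correlation, where fry called 14. Among genes whose 3' UTR lacks the scan's hexamers, tested with camera at the preset correlation only, 5 of 28 lists were called: HOX (adjusted p = 0.000201), stress response (adjusted p = 2.04e-07), ribosomal (adjusted p = 2.21e-05) and cholesterol genes (adjusted p = 0.0165), and mitosis genes, up, which were not called on all genes. The NRF2 call ended (adjusted p = 0.26) on the 5 of 17 genes left, whose median was 0.01 (quartiles -0.13 and 0.16) against -0.13 (-0.30 and 0.01) for all 17. The neuronal call ended (adjusted p = 0.0577) on 17 of 29 genes, with a median of -0.22 (quartiles -0.72 and 0.22) against -0.41 (-0.98 and -0.13). The fatty acid list had too few such genes for the test, and ELOVL5 and SCD hold a heptamer of the PHF12 scan's motif.

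**Figure D2:**
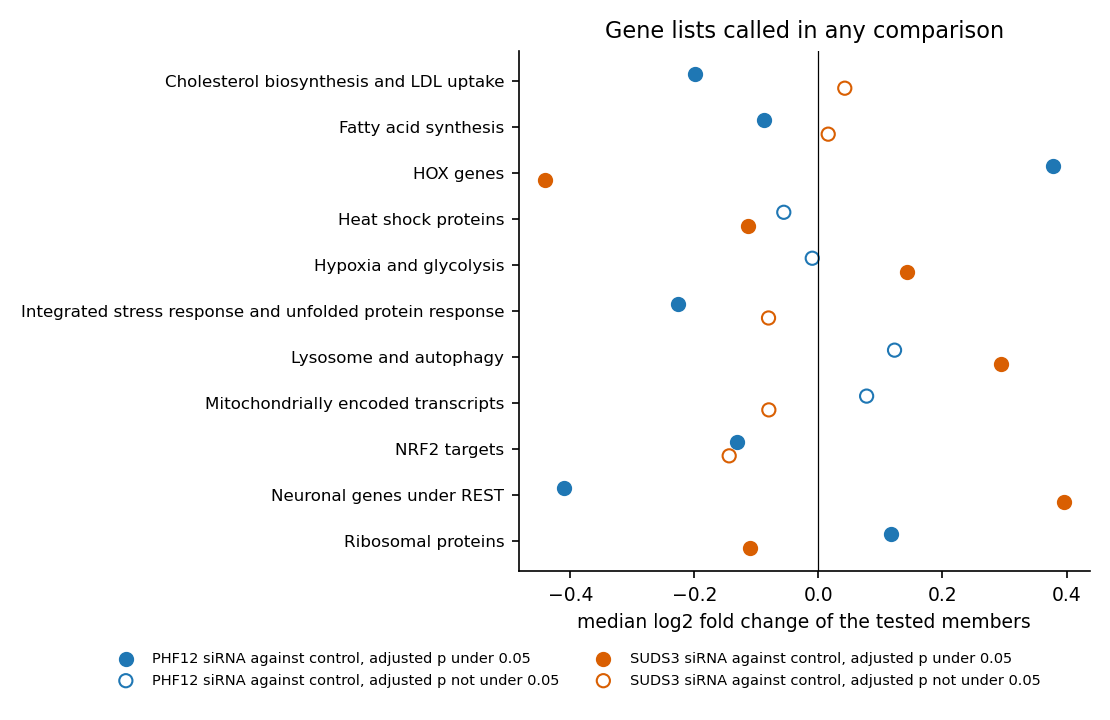
Median log2 fold change of the gene lists (y axis) that passed camera in at least 1 contrast, with each knockdown against control on the x axis and 1 point per knockdown; filled points passed in that knockdown and open points did not. HOX genes lay at 0.38 with the PHF12 siRNA and at -0.44 with the SUDS3 siRNA, and neuronal genes under REST at -0.41 and 0.40.

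The comparison of SUDS3 knockdown with control asks the same of the SUDS3 siRNA. In camera at the preset correlation, neuronal genes under REST and genes of lysosomes and autophagy rose as groups, and HOX genes and ribosomal protein genes fell. With an estimated correlation the neuronal and HOX calls held, each with an adjusted p of 0.0285, and the lysosome call (adjusted p = 0.0551) and the ribosomal call (adjusted p = 0.571) were lost. The largest rise was that of RUNDC3A (ENSG00000108309, chromosome 17, 44308413 to 44318671), a protein of neurons, from 1.31 ± 0.519 to 6.97 ± 0.897 CPM (log2 fold change 2.41, SE 0.24, adjusted p = 2.47e-10). Apart from SUDS3 itself, the largest fall was that of CFAP97, from 40.9 ± 0.601 to 9.97 ± 0.958 CPM (log2 fold change -2.04, SE 0.08, adjusted p = 3.81e-21). In all, 3537 genes rose, 3467 fell and 11084 did not pass, and at least 2-fold changes numbered 95 rises and 379 falls. Rises made up 50.5% of the calls with TMM scaling and 44.2% with upper-quartile scaling.

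Large rises with the SUDS3 siRNA were in UNC13A (log2 fold change 2.28), which primes synaptic vesicles, chromogranin A, CHGA (1.97), a protein of secretory granules, DISP2 (1.56), LMLN (1.54), the presynaptic scaffold BSN (1.52), the calcium channel CACNA1B (1.37), BICDL1 (1.37), TMEM52 (1.32) and CPLX1 (1.29). The largest adjusted p among them was 9.58e-06, that of CACNA1B. Large falls were in RCBTB2 (-2.01), neuroplastin, NPTN (-1.85), HDGFL3 (-1.84), the TGF-beta receptor TGFBR1 (-1.74), TBC1D5 (-1.73), PTGES3 (-1.73), a cochaperone of HSP90 with pseudogenes that can share reads, SUMO3 (-1.69) and the peptidase DPP4 (-1.68). PTGES3 fell from 868.7 ± 42.2 to 262.4 ± 12.8 CPM. The SUDS3 scan's hexamer TACATT was in the 3' UTR of 9 of the 10 largest falls, SUDS3 included and DPP4 excepted, and of 2 of the 10 largest rises. It too was picked from the same fold changes.

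Of 31 lysosome and autophagy genes, 26 rose with the SUDS3 siRNA, 2 fell and 3 did not pass, the same as adjusted over the list alone. Their median log2 fold change was 0.29 (camera adjusted p = 6.01e-09, and adjusted p = 0.0551 with an estimated correlation). The protective protein cathepsin A, CTSA, rose from 69.3 to 107.9 CPM (0.64) and the proton pump subunit ATP6V0D1 by 0.44. Among 29 neuronal genes under REST, 14 rose, 2 fell and 13 did not pass (15 rose and 2 fell adjusted over the list alone), with a median of 0.40 (adjusted p = 5.96e-06, and adjusted p = 0.0285 with an estimated correlation). SYP rose from 35.1 to 77.9 CPM, STMN3 by 1.01 on the log2 scale and the neurofilament gene NEFM by 0.40. Of 38 HOX genes, 23 fell, 2 rose and 13 did not pass, the same as adjusted over the list alone, with a median of -0.44 (adjusted p = 5.83e-08, and adjusted p = 0.0285 with an estimated correlation). HOXB2 fell from 23.4 to 11.8 CPM (-0.99), HOXC4 fell by 0.69 and HOXA10 by 0.62.

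Ribosomal protein genes fell in 52 of 78 cases with the SUDS3 siRNA, rose in 2 and did not pass in 24 (54 fell and 3 rose adjusted over the list alone), with a median of -0.11 (camera adjusted p = 3.05e-05, and adjusted p = 0.571 with an estimated correlation). RPL10 fell by 0.27, RPL24 by 0.26 and RPL6 by 0.23, and all 3 have pseudogenes that can share reads. Of 34 hypoxia and glycolysis genes, 18 rose, 5 fell and 11 did not pass (19 rose and 5 fell adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0101, and adjusted p = 0.571 with an estimated correlation). Hexokinase 2, HK2, rose by 0.49, as did BNIP3, and BNIP3L rose by 0.56. Of 18 heat shock protein genes, 8 fell, 2 rose and 8 did not pass (10 fell and 3 rose adjusted over the list alone), with a median of -0.11 (adjusted p = 0.028, and adjusted p = 0.497 with an estimated correlation). HSPD1, which has pseudogenes, fell by 0.52, CHORDC1 by 0.56 and HSP90AA1 from 3141 to 2547 CPM (-0.30).

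With the SUDS3 siRNA, camera called 6 of 32 lists, 2 of them (HOX and neuronal) with an estimated correlation, where fry called 20; the heat shock call ended without control replicate 2 (adjusted p = 0.0509) or SUDS3 knockdown replicate 2 (adjusted p = 0.0865). Among genes whose 3' UTR lacks the scan's hexamers, the HOX (adjusted p = 1.24e-05), neuronal (adjusted p = 3.12e-06), ribosomal (adjusted p = 3.38e-07), lysosome (adjusted p = 0.013) and heat shock calls (adjusted p = 0.0183) held. The lysosome median was lower on the 19 of 31 genes left, at 0.19 (quartiles 0.10 and 0.38) against 0.29 (0.17 and 0.41). The hypoxia call ended (adjusted p = 0.999) on 15 of 34 genes, with a median of 0.02 (quartiles -0.06 and 0.18) against 0.14 (0.00 and 0.33) for all 34.

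Subunits of the SIN3 complex itself changed in both knockdowns, without a shift of the list as a whole that camera called. The list's median log2 fold change was 0.08 with the PHF12 siRNA and 0.19 with the SUDS3 siRNA. With the PHF12 siRNA, 11 of 27 rose, 7 fell and 9 did not pass (12 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.765). HDAC1, the catalytic deacetylase, rose from 276.3 ± 2.59 to 408.1 ± 12.4 CPM (log2 fold change 0.56, SE 0.03, adjusted p = 2.08e-17), while the partner FOXK2 fell by 0.74 on the log2 scale. BRMS1L (0.29), ARID4A (0.29), RBBP7 (0.26), KDM5A (0.22), TET1 (0.21), FOXK1 (0.19), SAP30L (0.19), ARID4B (0.13), MORF4L1 (0.11) and SAP18 (0.10) rose as well. Besides PHF12, SUDS3 and FOXK2, falls were in SINHCAF (-0.32), GATAD1 (-0.20), SAP30 (-0.20) and OGT (-0.09). With the SUDS3 siRNA, 16 of 27 rose, 5 fell and 6 did not pass (16 rose and 6 fell adjusted over the list alone; adjusted p = 0.556). BRMS1L, a paralog of SUDS3, fell from 59.9 ± 1.96 to 27.9 ± 1.49 CPM (log2 fold change -1.10, SE 0.06, adjusted p = 9.92e-18), and its 3' UTR holds the SUDS3 scan's octamer GTACATTA. TET1 (0.61), ING2 (0.55), SAP130 (0.49), BRMS1 (0.40), SAP30L (0.38), EMSY (0.36), SAP30 (0.35), ARID4A (0.35), ARID4B (0.33), SIN3A (0.31), SIN3B (0.25), ING1 (0.22), FOXK1 (0.19), FOXK2 (0.18) and HDAC1 (0.10) rose, beside PHF12. SINHCAF (-0.35), RBBP7 (-0.16) and MORF4L1 (-0.08) fell, beside SUDS3 and BRMS1L.

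Several small SIN3 calls ended in fits without 1 library, with log2 fold changes that kept their direction. With the PHF12 siRNA, the fall of SAP30 (adjusted p = 0.0484 in the fit of all libraries) ended without any library except control replicate 2 and PHF12 knockdown replicate 2, with log2 fold changes of -0.21 to -0.11 (adjusted p up to 0.355, without control replicate 3). The rise of SAP30L ended without control replicate 1 (0.10, adjusted p = 0.345) or PHF12 knockdown replicate 1 (0.11) or 2 (0.20). That of SAP18 ended without control replicate 1 or 3 or PHF12 knockdown replicate 2 or 3, at 0.09 to 0.10 (adjusted p up to 0.164). That of ARID4B ended without control replicate 1 (0.10) or 2 (0.13) or PHF12 knockdown replicate 2 (0.07, adjusted p = 0.293). The fall of OGT ended without control replicate 2 or 3, PHF12 knockdown replicate 1 or 2 or SUDS3 knockdown replicate 2, which is outside the contrast, at -0.09 to -0.07 (adjusted p up to 0.21). The rise of TET1 ended without control replicate 3 or PHF12 knockdown replicate 2 or 3, at 0.16 to 0.20 (adjusted p up to 0.117). With the SUDS3 siRNA, the rise of ING1 ended without control replicate 1 or 3 or SUDS3 knockdown replicate 1 or 3, at 0.15 to 0.23 (adjusted p up to 0.247). The fall of MORF4L1 ended without control replicate 2 or SUDS3 knockdown replicate 1 or 2, at -0.08 to -0.07 (adjusted p up to 0.0814).

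Other settings also ended small SIN3 calls without a change of direction. The fall of SAP30 with the PHF12 siRNA ended with replicate number as a block (-0.20, adjusted p = 0.0531), RLE (adjusted p = 0.0645) and upper-quartile scaling (-0.16, adjusted p = 0.122), fits of 2 groups (adjusted p = 0.0684), no low-count filter, counts divided by 4 and TPM (-0.14, adjusted p up to 0.323). That of OGT ended with upper-quartile scaling (-0.05, adjusted p = 0.284), RLE scaling, no low-count filter, no robust shrinkage, DESeq2 and TPM (adjusted p up to 0.322). The rise of SAP18 ended with no low-count filter (adjusted p = 0.0633) and no robust shrinkage (adjusted p = 0.054). On TPM the rises of SAP30L (adjusted p up to 0.231) and ARID4B (adjusted p up to 0.2) ended, as did that of FOXK1 without the TPM filter (adjusted p = 0.0678). With the SUDS3 siRNA, upper-quartile scaling ended the rises of HDAC1 (0.07, adjusted p = 0.0814) and ING1 (0.20, adjusted p = 0.075). That of ING1 ended on TPM as well (adjusted p up to 0.13), and the fall of MORF4L1 with no low-count filter (adjusted p = 0.0545) and on TPM (-0.06, adjusted p up to 0.118).

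The comparison of SUDS3 with PHF12 knockdown asks where the effects of the siRNAs differ, and the controls cancel from it. In camera at the preset correlation, HOX and ribosomal protein genes were lower with the SUDS3 siRNA than with the PHF12 siRNA, and neuronal, lysosomal, cholesterol and hypoxia genes were higher. With an estimated correlation the HOX call (adjusted p = 0.00578) and the neuronal call (adjusted p = 0.00858) held, and the others were lost, with an adjusted p of 0.232 for ribosomal, 0.127 for lysosomal, 0.0907 for cholesterol and 0.59 for hypoxia genes. The largest single differences were in genes that moved in opposite directions. SLC4A8 stood at 12.96 ± 1.39 CPM with the PHF12 siRNA and 1.36 ± 0.0967 CPM with the SUDS3 siRNA, against 2.63 in controls (difference -3.25 in log2, SE 0.17, adjusted p = 5.35e-18), although its fall with the SUDS3 siRNA was not called on TPM without a filter (-0.10 as log2(TPM + 1), adjusted p = 0.13). CHGA (chromosome 14, 92923080 to 92935293) stood at 0.985 ± 0.300 CPM with the PHF12 siRNA and 8.91 ± 1.56 CPM with the SUDS3 siRNA, against 2.27 in controls (difference 3.17, SE 0.22, adjusted p = 1.51e-14). In this contrast 4113 genes were higher with the SUDS3 siRNA, 3824 were lower and 10151 did not pass, with 324 and 595 at least 2-fold. Higher genes made up 51.8% of the calls with TMM scaling and 41.2% with upper-quartile scaling.

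Other genes much higher with the SUDS3 siRNA were CPLX1 (difference 3.10), HMGA2 (3.00), RUNDC3A (2.82) and UNC13A (2.49). Much lower ones were SYT11 (-3.10), C16orf45 (-2.87), MAP6 (-2.53) and HAS2 (-2.09), which makes hyaluronan. Of 38 HOX genes, 29 were lower, 2 higher and 7 did not pass (30 lower and 2 higher adjusted over the list alone), with a median difference of -0.81 (camera adjusted p = 9.37e-18, and adjusted p = 0.00578 with an estimated correlation). HOXA10 differed by -1.09, HOXA5 by -0.95 and HOXA3 by -1.36. Among 29 neuronal genes under REST, 16 were higher, 4 lower and 9 did not pass (17 higher and 4 lower adjusted over the list alone), with a median of 0.85 (adjusted p = 2.83e-08, and adjusted p = 0.00858 with an estimated correlation). CPLX1, SYP (1.97) and STMN3 (2.00) were the leading members. Ribosomal protein genes were lower in 68 of 78 cases, higher in 1 and did not pass in 9 (70 lower and 1 higher adjusted over the list alone), with a median of -0.21 (adjusted p = 1.37e-12, and adjusted p = 0.232 with an estimated correlation). RPS25 (-0.45), RPL26 (-0.39) and RPL24 (-0.36) led them.

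Of 31 lysosome and autophagy genes, 21 were higher with the SUDS3 than with the PHF12 siRNA, 4 lower and 6 did not pass, the same as adjusted over the list alone, with a median of 0.18 (camera adjusted p = 4e-06, and adjusted p = 0.127 with an estimated correlation). ATP6V1A (1.83), NEU1 (1.63) and MAP1LC3B (1.37) led them, and each had fallen with the PHF12 siRNA, by 1.53, 1.34 and 1.18. Cholesterol genes were higher in 15 of 25 cases, lower in 5 and did not pass in 5 (16 higher and 5 lower adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00354, and adjusted p = 0.0907 with an estimated correlation), with LSS (1.11) and DHCR7 (0.57) among the leading members. Of 34 hypoxia and glycolysis genes, 16 were higher, 6 lower and 12 did not pass (18 higher and 6 lower adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0174, and adjusted p = 0.59 with an estimated correlation), led by HK2 (0.91), MXI1 (0.82) and KDM3A (0.79). Of 13 mitochondrially encoded transcripts, 9 were lower, 0 higher in edgeR, also at an unadjusted p under 0.05 and in DESeq2, and 4 did not pass, the same as adjusted over the list alone, with a median of -0.16 (adjusted p = 0.00547, and adjusted p = 0.585 with an estimated correlation). MT-ND6 (-0.40), MT-ND2 (-0.26) and MT-ATP8 (-0.34), which overlaps a neighbouring gene, were among them. Among SIN3 subunits 14 of 27 were higher, 7 lower and 6 did not pass, the same as adjusted over the list alone (adjusted p = 0.86), with the widest gaps, outside PHF12 and SUDS3, in BRMS1L (-1.39) and FOXK2 (0.92). Lists called in 1 knockdown alone were not all shown to differ between the knockdowns: adjusted p was 0.0591 for the stress response list, 0.0812 for NRF2 targets, 0.12 for fatty acid synthesis and 0.676 for heat shock proteins.

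Between the knockdowns camera called 7 of 32 lists, 2 of them (HOX and neuronal) with an estimated correlation, where fry called 22, and the hypoxia call ended with counts divided by 4 (adjusted p = 0.0549). Among genes whose 3' UTR lacks the scan's hexamers, the HOX (adjusted p = 1.17e-10), neuronal (adjusted p = 9.22e-08) and ribosomal calls (adjusted p = 4.78e-14) held, and mitochondrially encoded transcripts were not in this test. The lysosome call ended (adjusted p = 0.583) on 19 of 31 genes, with a median of 0.16 (quartiles -0.02 and 0.34) against 0.18 (0.03 and 0.48). The cholesterol call ended (adjusted p = 0.432) on 11 of 25 genes, at 0.19 (quartiles 0.05 and 0.26) against 0.22 (0.07 and 0.39). The hypoxia call ended (adjusted p = 0.855) on 15 of 34 genes, at 0.03 (quartiles -0.13 and 0.17) against 0.15 (0.02 and 0.36). With RLE and upper-quartile scaling, each called list kept the sign of its median in the contrast in which it was called. With upper-quartile scaling the median moved by over 1.5 times for fatty acid genes with the PHF12 siRNA (from -0.09 to -0.05) and, between the knockdowns, for hypoxia (from 0.15 to 0.08) and lysosome genes (from 0.18 to 0.12).

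Some genes moved the same way in both knockdowns. LMLN rose from 5.13 ± 0.508 CPM in controls to 13.8 ± 0.837 with the PHF12 siRNA and 14.96 ± 1.33 with the SUDS3 siRNA (log2 fold changes 1.42 and 1.54). CCDC173 (1.29 and 1.01), the GTPase RAB36 (0.99 and 0.84), the myosin phosphatase partner MPRIP (0.78 and 1.02) and ZNF385A (0.90 and 0.78) also rose in both. TPD52 fell from 69.9 ± 3.05 CPM to 20.3 ± 1.07 and 23.1 ± 1.61 (-1.78 and -1.60), and ELAVL2 (-1.32 and -1.55), a neuronal RNA-binding protein, and SLC39A6 (-1.84 and -0.91) fell in both, with SUDS3. TPD52, SLC39A6 and SUDS3 are among the genes described above whose 3' UTR holds the PHF12 scan's hexamer AATCAC. In total 1059 genes rose in both, against 524.1 for independent lists of these sizes, and 998 fell in both, against 593.4. Opposite movements numbered 550 genes that rose with the PHF12 siRNA and fell with the SUDS3 siRNA, against 513.7, and 741 the other way, against 605.4. With upper-quartile scaling their order turned, to 814 and 501 genes. The numbers for independent lists take every tested gene as equally likely to pass, without regard to expression level. Genes that pass easily in both contrasts can thus raise every class above them, so the excess does not show that opposite movement was favoured. Observed numbers were 2.02 and 1.68 times those for independent lists in the same direction, and 1.07 and 1.22 times in opposite directions. The simulations with shared controls and unchanged groups gave at most 0 genes with edgeR in either same-direction class, and at an unadjusted p under 0.05 at most 112 rises and 78 falls. With no gene changed, almost none passes the adjusted threshold, so they do not show how much shared controls added to the observed overlaps.

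Across the 18088 tested genes, which are not independent replicates, the covariance of both log2 fold changes was 0.069, against 0.0465 to 0.0607 in the simulations, and their correlation was 0.253 against a mean of 0.521. The covariance was 0.225, 0.217 and 0.203 without control replicate 1, 2 or 3, 0.109 and 0.104 without PHF12 knockdown replicate 2 or 3, and lower than these without any other library. Each fit without 1 library chose its genes anew by the low-count filter, and all 9 covariances, 0.0897 to 0.225, lay above 0.069. The SE over libraries left out, 0.154, thus mixes a changed set of genes with the spread between libraries. It cannot decide whether the excess of 0.0165 over the simulated mean lies beyond that spread. Among the 12728 genes with an average log2 CPM of at least 1, the covariance was 0.0168 against a simulated maximum of 0.0062, and lay between 0.0153 and 0.0209 without any single library.

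**Figure D3:**
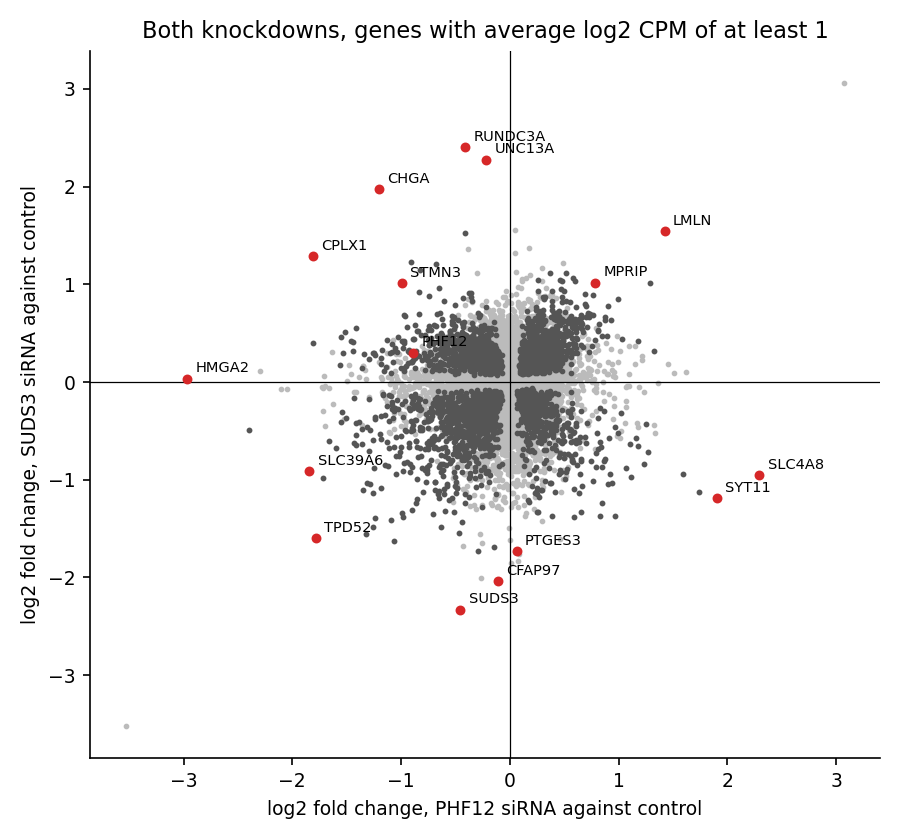
Log2 fold change with the PHF12 siRNA (x axis) and with the SUDS3 siRNA (y axis) for the 12728 genes with an average log2 CPM of at least 1, 1 point per gene; dark points passed in both contrasts, light points did not, and labelled red points are a choice of the named genes. SLC4A8 (2.29 and -0.95) and CHGA (-1.20 and 1.97) lie in opposite corners, LMLN at the upper right, and the light points furthest out, the pseudogenes RPS3AP5 (3.07 and 3.06) and NPM1P6 (-3.53 and -3.52), did not pass.

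The 3' UTR scan gave a different leading heptamer for each siRNA. With the PHF12 siRNA, the 1710 genes whose 3' UTR holds AATCACA shifted down with a z of -21.8, and with the SUDS3 siRNA the 1696 genes with GTACATT did so with a z of -20.6. Scored in the other knockdown, AATCACA had a z of -0.817 and GTACATT one of 1.12. Genes with the octamer CAATCACA had a median log2 fold change lower by 0.27 than genes without its hexamer with the PHF12 siRNA (difference -0.27, 95% interval -0.34 to -0.23, 324 genes). Genes with GTACATTA differed by -0.39 with the SUDS3 siRNA (95% interval -0.50 to -0.33, 331 genes); this octamer replaced TGTACATA, built on another hexamer of the leading heptamer, after that gave -0.07 for 1031 genes. These differences are not adjusted for 3' UTR length. Each motif was picked from the fold changes of its own knockdown, so its difference and shares of falls there are no separate test of it. In the other knockdown the differences were -0.09 for CAATCACA (95% interval -0.13 to -0.02) and -0.05 for GTACATTA (95% interval -0.09 to -0.01). Of the falls with the PHF12 siRNA among scanned genes, 1585 of 2843 (55.8%) held the PHF12 scan's hexamer, and of those of at least 2-fold 133 of 155 (85.8%), against 31.7% of all scanned genes. For the SUDS3 scan's hexamer these were 1688 of 2957 (57.1%) and 97 of 142 (68.3%), against 42.9%.

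**Figure D4:**
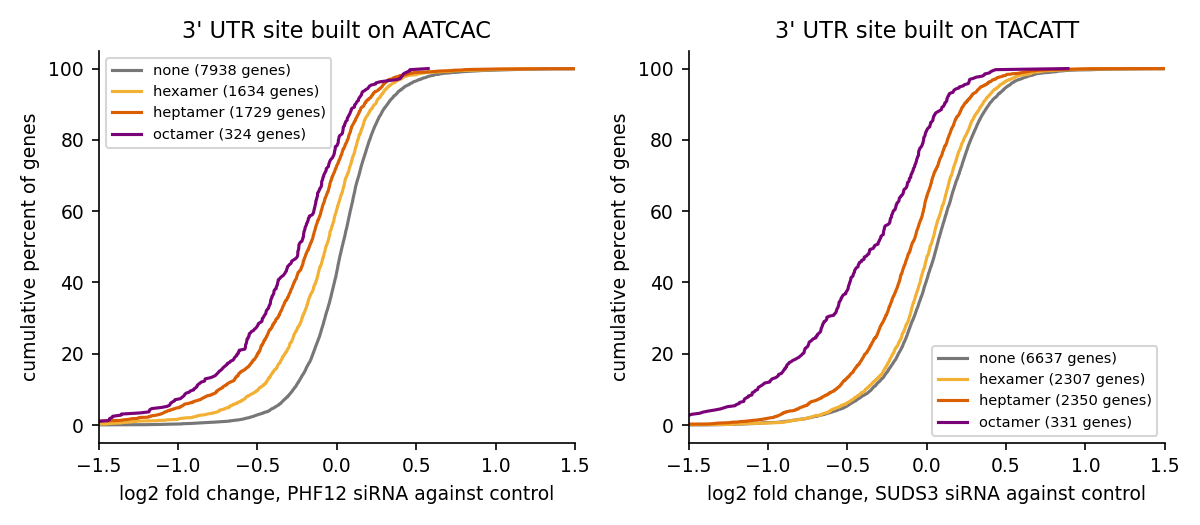
Cumulative share of genes (y axis) by log2 fold change against control (x axis) for genes whose longest annotated 3' UTR holds the octamer, a heptamer, the hexamer alone or none of them; the PHF12 siRNA with its scan's motif is on the left and the SUDS3 siRNA on the right. The octamer classes of 324 and 331 genes lie furthest left, with medians of -0.24 and -0.33, against 0.03 and 0.06 for the 7938 and 6637 genes without the hexamer.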

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

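The 3' UTR scan and the tests that use its motifs were chosen after the data were examined. Of these, tests of the shift of octamer genes and of heptamers sharing no hexamer with the leading one, the base composition value for the rebuilt SUDS3 hexamer, and the interval and the larger rises set beside the share of rises without the hexamer, were chosen after results of the scan's motifs were seen. The simulations with shared controls and the splits of the libraries were planned. Each motif was picked for its z on the same fold changes, so its shifts and shares there are no separate test of seed pairing. Genes whose 3' UTR lacks the hexamers can hold them in the coding sequence. Calls that held among those genes, lists included, therefore do not exclude seed pairing.

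Each result that follows stands out because the effects of the PHF12 and SUDS3 siRNAs, each against the same controls, differed from each other in the direct contrast. The test was the edgeR F-test for single genes and camera at the preset correlation for lists, which does not test the median. SLC4A8 was lower with the SUDS3 siRNA than with the PHF12 siRNA by -3.25 in log2 (adjusted p = 5.35e-18). CHGA was higher by 3.17 (adjusted p = 1.51e-14). SYT11 was lower, at -3.10 (adjusted p = 6.38e-18). CPLX1 was higher by 3.10 (adjusted p = 3.55e-18). C16orf45 was lower, at -2.87 (adjusted p = 2.12e-12). The median difference was -0.81 for HOX genes (adjusted p = 9.37e-18, and adjusted p = 0.00578 with an estimated correlation). For neuronal genes under REST it was 0.85 (adjusted p = 2.83e-08, and adjusted p = 0.00858 with an estimated correlation). For ribosomal protein genes it was -0.21 (adjusted p = 1.37e-12, and adjusted p = 0.232 with an estimated correlation).

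Falls with the PHF12 siRNA went with the sequence AATCACA in the 3' UTR. Seed pairing of the siRNA with these 3' UTRs may explain part of them: octamer genes differed from genes without the hexamer by -0.27 in median log2 fold change (by -0.09 with the SUDS3 siRNA), beyond the -0.21 of heptamer genes and the -0.10 of genes with the hexamer alone, and the heptamer lies in the coding sequence of 3 of 3 coding transcripts of PHF12, although 16.7% of all heptamers lie in that sequence and 35.2% anywhere in these transcripts. Base composition was tested by the largest absolute z among heptamers of the same bases without the hexamer, 0.51 of the leading one, which met the bound set for that explanation, but its heptamer, ATCACAA, shares the hexamer ATCACA with the leading one and so cannot decide. Among heptamers sharing no hexamer with it the value was 0.266, which argues against composition as the whole cause. Loss of PHF12 stays open for the rest. The 3' UTR lacks the hexamer in 44.2% of the falls (1258 of 2843) and in 14.2% of those of at least 2-fold. Such genes can hold it in the coding sequence, so these shares are not free of candidate sites. The 166 genes with the octamer only there differed by -0.18 from genes with the hexamer in neither place (bootstrap interval -0.24 to -0.10). The difference was -0.06 for the heptamer only there (700 genes) and -0.02 for the hexamer (interval -0.04 to 0.01). With 1 siRNA per target, loss of PHF12 and seed pairing cannot be told apart gene by gene.

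Falls with the SUDS3 siRNA went with GTACATT in the same manner. Octamer genes differed by -0.39 (by -0.05 with the PHF12 siRNA), against -0.16 for heptamer genes and -0.04 for hexamer genes, and the heptamer lies in the coding sequence of 1 of 1 coding transcripts of SUDS3 (5.47% of all heptamers lie in that sequence and 23.6% anywhere in the transcript), so seed pairing is a candidate explanation. The octamer was first built on the hexamer GTACAT, which gave -0.07 for TGTACATA, and was rebuilt to hold the leading heptamer after that value was seen. For base composition the value was 0.455 with the rebuilt hexamer left out, from a heptamer that shares the hexamer GTACAT with the leading one, 0.253 with GTACAT left out and 0.152 for heptamers sharing neither, which argues against it as the whole cause. Loss of SUDS3 stays open, since 42.9% of the falls (1269 of 2957) and 31.7% of those of at least 2-fold lack the hexamer. Here too such genes can hold it in the coding sequence. The 61 genes with the octamer only there differed by -0.10 (bootstrap interval -0.19 to -0.01). The difference was -0.02 for the heptamer only there (interval -0.05 to 0.01) and 0.02 for the hexamer.

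Rises with both siRNAs were weighed because the control siRNA is the one treatment absent from both. Shared control values alone, with no gene changed, gave at most 0 such genes in simulations with edgeR (112 at an unadjusted p under 0.05), against 1059. With no gene changed, almost none passes the adjusted threshold, so this does not exclude a part of shared control values. Genes changed in 1 knockdown, which such values could carry past the threshold in the other, were not simulated. Release from seed pairing of the control siRNA was weighed with AGCAACC, the leading heptamer of the rises (z 7.46). Octamer genes shifted by 0.036 with the PHF12 siRNA and by 0.032 with the SUDS3 siRNA (95% intervals of -0.01 to 0.07 and -0.01 to 0.08). Both shifts lay under the bound of 0.05 that was set as counting against this explanation. Neither reached the shift of over 0.1 in each knockdown that was set as counting for it. Both intervals reach past 0.05 but not 0.1. They argue against a shift as large as the one set for this explanation, while a smaller part stays open. A heptamer or octamer of the motif was in 18.4% of the scanned rises and in 40.7% of the 27 of at least 1.5-fold in both, against 12.3% of genes. The motif was picked from the same fold changes, so these shares do not test the explanation. A shared effect of losing either subunit, or any other cause not tied to the hexamer, stays open for part of the rises, but 68.8% of them lack the hexamer (95% Wilson interval 65.8% to 71.5%) and 51.9% of those 27, against 75.6% of all scanned genes, where a cause tied to neither the hexamer nor 3' UTR length would alone give an equal share. A response to the transfection of any active siRNA was not tested.

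Each comparison was set beside all 10 splits of its 6 libraries into groups of 3, fitted on those 6 libraries, where the share of splits as large as the real one is never under 0.1. Every other split puts libraries of both siRNAs in each group, so a real effect widens the spread within groups and lowers their calls. Low numbers for these splits are therefore not a measure of chance alone. For PHF12 knockdown the real split called 5855 genes and the highest of the others 0 with edgeR, so 1 of the 10 splits was as large. For SUDS3 knockdown these numbers were 6879 and 0, also 1 of the 10 splits. Between the knockdowns they were 7941 and 0, again 1 of the 10 splits. At an unadjusted p under 0.05 the other splits called at most 325, 304 and 207 genes, against 7180, 7993 and 8911.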

How the results depend on the processing

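Alternatives with counts divided by 4, with genes lacking the hexamers and with a minimum average log2 CPM for the covariance were chosen after the data were examined. Of the counts, fold changes of the targets, overlaps and numbers of called lists, 399 values under alternatives stayed within 1.5 times the reported count or within the spread, and 42 moved further. Among genes whose 3' UTR holds none of the hexamers (5798 genes), fewer are tested by construction: 1207 rose and 780 fell with the PHF12 siRNA (54 and 26 at least 2-fold), 1566 and 1019 with the SUDS3 siRNA (35 and 93), and 1431 and 1360 differed between them (63 and 195). The overlaps there were 507 rises and 212 falls in both, 204 and 232 in opposite directions, and 3 lists were called between the knockdowns. Pseudocounts on TPM shrink large changes by construction: with log2(TPM + 1), 2-fold rises and falls numbered 26 and 103 (PHF12), 27 and 88 (SUDS3), 152 and 156 (between them), and without the TPM filter 20 and 98, 24 and 83, 151 and 150. With log2(TPM + 0.1), 2-fold rises numbered 64 with the PHF12 siRNA, 2-fold rises and falls 50 and 199 with the SUDS3 siRNA, and 298 genes were at least 2-fold lower between them. DESeq2 gave 153 rises of at least 2-fold with the SUDS3 siRNA, and the cause was not tested. With counts divided by 4, more genes rose and fell (2966 and 3152 with the PHF12 siRNA, 3626 and 3560 with the SUDS3 siRNA). Fewer did so at least 2-fold: 107 and 207, then 75 and 303, and 282 and 464 between the knockdowns. The covariance was 1.42 without a filter on low counts and 0.0202 with counts divided by 4. At an average log2 CPM of at least 1 it was 0.0168. These last 2 counted as within the spread only by the SE of 0.154. Without single libraries, where the filter chose genes anew, it lay between 0.0897 and 0.225. Camera with an estimated correlation called 0, 2 and 2 lists and fry 14, 20 and 22. On the 15 hypoxia genes without the hexamers camera pointed down, but with an adjusted p of 0.999 for SUDS3 knockdown and 0.855 between the knockdowns and medians of 0.02 and 0.03, which show no direction. Without single libraries, 2254 to 2790 genes rose and 2650 to 3034 fell with the PHF12 siRNA, and 3075 to 3527 and 2981 to 3416 with the SUDS3 siRNA. Named genes kept direction and side of the threshold in 5880 of their values under alternatives and lost the call in 142; lists kept it in 273, lost it in 23 and turned in 2; the octamer differences kept direction and size in 42 of 42. No pairing by replicate number was visible. Residuals of libraries with the same number correlated between -0.127 and 0.135, and those with different numbers between -0.156 and 0.147. This does not exclude that libraries were prepared in pairs or batches. Replicate number as a block gave 2740 rises and 3108 falls with the PHF12 siRNA and, among named genes and lists, ended the call of SAP30 with the PHF12 siRNA alone. At the depth of these libraries the fit missed part of the simulated changes of each size: of 50 genes changed 1.5-fold, 23 and 28 were recovered in the PHF12 and SUDS3 arms, and of 50 changed 3-fold 40 and 43, so a gene that did not pass may still have changed.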

Other observations

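The test on REST in this part was chosen after its values were seen, and the tests on genes without the hexamers were chosen after the data were examined.

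On all tested genes, growth and division genes changed without a shift of their lists called by camera, whose adjusted p is given below. With the SUDS3 siRNA, fry called the G1/S (fry adjusted p = 0.0172), respiratory chain (0.0328) and histone lists (0.0011). Of 54 genes of DNA replication and the G1/S transition, 19 rose and 16 fell with the PHF12 siRNA (camera adjusted p = 0.834), and 8 rose and 24 fell with the SUDS3 siRNA (adjusted p = 0.121). Of 54 genes of mitosis, 22 rose and 9 fell (adjusted p = 0.105), and 19 rose and 11 fell (adjusted p = 0.63). On the 28 of them whose 3' UTR lacks the hexamers, the list was called up with the PHF12 siRNA (camera adjusted p = 0.0445, median 0.09, against 0.07 for all 54). That call used the preset correlation only. With an estimated correlation, camera on all 54 gave an adjusted p of 0.722. Of 50 ribosome biogenesis genes, 5 rose and 14 fell with the PHF12 siRNA (adjusted p = 0.518), and 18 rose and 12 fell with the SUDS3 siRNA (adjusted p = 0.65). Among 66 nuclear-encoded respiratory chain genes, 11 rose and 7 fell (adjusted p = 0.947), and 5 rose and 15 fell (adjusted p = 0.469). Replication-dependent histone genes had 2 rises and 0 falls of 15 with the PHF12 siRNA in edgeR, with 1 fall at an unadjusted p under 0.05 and 1 in DESeq2 (median -0.12, while camera pointed up; adjusted p = 0.569). With the SUDS3 siRNA they had 3 falls and 0 rises in edgeR, also at an unadjusted p and in DESeq2 (adjusted p = 0.301). Poly-A selection captures most of these transcripts poorly.

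Signalling lists were also not called by camera, whose adjusted p is given for each list below. With the PHF12 siRNA, fry called Wnt (fry adjusted p = 0.000288), p53 (0.00369) and Notch and Hes targets (0.0208). With the SUDS3 siRNA, fry called p53 targets (0.000192) and metallothionein (0.000163), TGF-beta response (0.00507) and extracellular matrix genes (0.0227). Of 30 p53 targets, 9 rose and 4 fell with the PHF12 siRNA (adjusted p = 0.431), and 12 rose and 9 fell with the SUDS3 siRNA (adjusted p = 0.147). Wnt targets had 1 rise and 8 falls of 19 (adjusted p = 0.0942), then 4 rises and 2 falls (adjusted p = 0.688). Notch and Hes targets had 1 rise and 6 falls of 19 (adjusted p = 0.518), then 4 rises and 5 falls (adjusted p = 0.63). TGF-beta response genes had 7 rises and 9 falls of 27 (adjusted p = 0.964), then 5 rises and 11 falls (adjusted p = 0.312). For 33 interferon response genes these were 5 and 4 (adjusted p = 0.569), then 5 and 9 (adjusted p = 0.761), and for 25 immediate early genes 3 and 6 (adjusted p = 0.835), then 4 and 6 (adjusted p = 0.641). Extracellular matrix genes had 10 rises and 16 falls of 57 (adjusted p = 0.431), then 10 and 24 (adjusted p = 0.121). Metallothioneins and metal response genes had 3 rises and 2 falls of 8 (adjusted p = 0.818), then 4 and 1 (adjusted p = 0.12).

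Chromatin, RNA interference and marker lists were not called by camera either, whose adjusted p is given below. With the PHF12 siRNA, fry called genes raised by HDAC inhibitors (fry adjusted p = 0.00114) and the blood cell (0.00195) and fibroblast markers (0.00636). With the SUDS3 siRNA, fry called germline (0.00243), NuRD and CoREST (0.0266) and RNAi genes (0.006) and the fibroblast markers (0.00228). Of 10 genes raised by HDAC inhibitors, 4 rose and 1 fell with the PHF12 siRNA (adjusted p = 0.0856), and 2 rose and 2 fell with the SUDS3 siRNA (adjusted p = 0.722). Germline genes under MGA and E2F6 had 1 fall of 11 (adjusted p = 0.939), then 4 falls (adjusted p = 0.376), and 0 rises in either knockdown in edgeR, also at an unadjusted p and in DESeq2. Their median with the PHF12 siRNA was 0.22 and their mean -0.09. NuRD and CoREST subunits had 4 rises and 2 falls of 19 (adjusted p = 0.569), then 4 and 6 (adjusted p = 0.63), and RNAi machinery 3 rises and 1 fall of 13 (adjusted p = 0.697), then 6 and 3 (adjusted p = 0.345). Lists of markers of other cells, with 5 tested genes each, had an adjusted p of 0.215 and 0.745 for blood cells, 0.507 and 0.439 for fibroblasts and 0.746 and 0.63 for keratinised epithelial cells with the PHF12 and the SUDS3 siRNA. The median, the mean or camera's direction differed in sign with the PHF12 siRNA for the G1/S, lysosome (10 rose, 4 fell, adjusted p = 0.947), hypoxia, respiratory chain, SIN3 and keratinised lists, with the SUDS3 siRNA for the fatty acid, Wnt and Notch lists, and between the knockdowns for the Notch, p53, immediate early and fibroblast lists.

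A hypothesis links the neuronal genes to REST (chromosome 4, 56907876 to 56966678), their repressor, which was singled out after its values were seen. REST fell by 0.48 on the log2 scale with the SUDS3 siRNA (log2 fold change -0.48, SE 0.06, adjusted p = 2.67e-08) and rose by 0.41 with the PHF12 siRNA (SE 0.06, adjusted p = 4.59e-07), from 49.5 ± 2.43 CPM in controls. The neuronal list moved the other way in each knockdown, with medians of 0.40 and -0.41. The SUDS3 call held with an estimated correlation (adjusted p = 0.0285) and on genes without the hexamers (adjusted p = 3.12e-06), while the PHF12 call was lost in both (adjusted p = 0.119 and 0.0577). On the genes without the hexamers 17 of the 29 were left, with a median of -0.22 with the PHF12 siRNA, so the lost call does not show that this shift was absent. The 3' UTR of REST holds the octamer GTACATTA, as do 2.85% of the scanned genes, and lacks the hexamer AATCAC. Seed pairing of the SUDS3 siRNA with REST may therefore have raised neuronal genes, but REST was picked for these values, so they do not test it. Loss of SUDS3, a subunit of the complex that REST recruits through SIN3A, could do the same, and with 1 siRNA per target these cannot be told apart. An siRNA against SUDS3 with another seed, or a reporter with the 3' UTR of REST, would be a test. RCOR1, a corepressor of REST also singled out after its values were seen, fell with the PHF12 siRNA (log2 fold change -0.62, adjusted p = 2.23e-11), where the neuronal genes fell too.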
